A study of Mus musculus with 30 samples.

How the data were processed

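RNA of mouse embryonic stem (ES) cells was measured on 30 Affymetrix arrays, 1 array per sample, in 10 groups made of 2 genotypes and 5 days. Per the labels, biotin-labelled cRNA was prepared from total RNA and hybridized by the standard protocol of the manufacturer. The deposited values are probe set intensity on a linear scale, rounded to whole numbers, with 1 column per array. The normalization method, the background correction and the probe set summary are not given in the sources used here. The array means, which lay between 331.8 and 363.6, make it likely that the arrays had already been brought to 1 scale. The median intensity was 10 or 11 on each array and the 25th percentile was 6 on every array. Both lie near the floor, so they say little about the scale of expressed genes. The 75th percentile ran from 82 to 106. Intensities ranged from 1 to 68951. Because array medians differed by at most 0.1 on the log2 scale, below the limit of 0.5 set for it, no further normalization was applied in the main comparisons.

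The table held 45101 probe sets. A gene was taken from the probe annotation for the 34958 probe sets that name 1 gene. The 932 probe sets with several genes and the 9211 without a gene were left out of the gene tests. Among all probe sets, 64 were controls of the manufacturer. Of the named probe sets, 34754 were matched by gene identifier to the gene table of mouse assembly GRCm38.p6, which changed 0 symbols; no positions were used. For the 9012 genes with several probe sets, the probe set with the highest mean log2 value over all arrays stood for the gene, which left 18194 genes. No gene was removed for low signal.

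Values were transformed to log2(intensity + 4), where 4 was the 5th percentile of the intensities. A fold change given here is 2 raised to a difference on that scale, so it understates the change of genes near the floor of the arrays. Group levels are mean intensities with the standard deviation (SD) between arrays. Differences are log2 changes with their standard error (SE). limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 30 arrays, with 20 residual degrees of freedom (20.6 in total after moderation). Each contrast was tested with limma's moderated test (two-sided), and p-values were adjusted over the 18194 genes by Benjamini-Hochberg, with a threshold of 0.05. A fit of all groups was chosen because 6 of the 10 groups held 2 arrays; the fit assumes that every group varies alike. The contrasts were null against Fl/Fl at each of the 5 days, null against Fl/Fl averaged over the days with each day weighted alike, day 8 against day 0 within each genotype, and the difference between those 2 changes. limma's moderated F test asked whether the genotype difference changed between any days.

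The 19 gene lists were tested with limma's camera, with the preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists. The lists were pluripotency and self-renewal, LIF and STAT3 response, primed epiblast, primitive and visceral endoderm, primitive streak and mesoderm, neuroectoderm, trophoblast, PRC2 and PRC1 subunits, Hox genes, non-Hox developmental regulators known as Polycomb targets, fibroblast and feeder cell markers, two-cell-like state, imprinted genes, germ cell genes, cell cycle and proliferation, p53 and stress response, glycolysis and hypoxia response, interferon response, and X and Y chromosome dosage. Some genes stand in several lists, such as Krt18 in the primed epiblast and trophoblast lists and Bmp4, Acta2 and Tagln in the mesoderm list. Camera compares a list with the other genes, so a list can pass it without any member passing by itself.

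The named genes followed a rule: Jarid2 and 25 fixed genes in every contrast, the 10 largest rises and falls in the averaged comparison, the courses and their difference, the 5 largest rises and falls per day among genes in which every null array lay on the same side of every Fl/Fl array, and up to 4 members per list with the smallest adjusted p. Of the 26 fixed genes, 24 were measured. Unnamed gene models were skipped. The groups, contrasts, tests, lists, naming rule and alternatives were chosen before the data were examined, except the list tests at days 2, 4 and 6 and the alternatives that use the level of Eif2s3y.

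The fit was tested on simulated data in which 100 of the 18194 genes were given a log2 change of 1 and another 100 a change of 2. For the averaged comparison it recovered 98% and 100%, for day 0 71% and 95%, for day 2 87% and 96%, for day 4 72% and 97%, for day 6 75% and 98%, and for day 8 59% and 98%. For the day 8 against day 0 change it recovered 58% and 91% in Fl/Fl, 76% and 96% in null, and 57% and 74% for the difference between them; the F test recovered 56% and 76%. Between 5 and 15 unchanged genes were called per comparison. A shift of 0.5 given to each list in turn was found for 19 of 19 lists, with 0 wrong lists called. The simulated noise was drawn independently for each gene and array, with the same spread of a gene on every array. It held no correlation between genes or arrays, so it does not show how the fit and camera fare where such correlation exists.

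The alternatives tried were quantile normalization, centring each array on its median, pseudocounts of 1 and 4 times the main one, removal of the 40% of genes with the lowest mean, the mean of the probe sets of a gene, a prior variance with a trend, array weights, a fit of only the arrays compared, null replicates 1 and 2 only, the replicate number as a block, a 2-fold limit beside the threshold, an estimated correlation for the lists, and each array left out in turn. After the data were seen, the comparisons were also run with subsets of the null arrays defined by the level of Eif2s3y. Replicate numbers were not used to pair samples. The number of arrays limits the precision of every value; the arrays give no count from which an interval could be computed.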

Results

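Gene expression was compared between mouse ES cells with floxed, intact Jmj alleles (Fl/Fl), which the labels call wild type, and Jmj-null ES cells. Jmj (Jumonji) is the gene now named Jarid2, which encodes a protein that binds PRC2, the complex that places a repressive methyl mark on histones. Differentiation was started by withdrawing LIF, the cytokine that holds mouse ES cells in the undifferentiated state, and RNA was taken on days 0, 2, 4, 6 and 8. Fl/Fl cells gave 2 arrays per day, 10 in all. Null cells gave 3 arrays at day 0, 5 each at days 2, 4 and 6, and 2 at day 8, 20 in all. The design asks how gene expression differs between the genotypes before differentiation and during it. Replicate arrays correlated across genes at Pearson's r of 0.991 to 0.9967 in Fl/Fl. In null the range was 0.9827 to 0.997 at days 0 to 6, and the pair of day 8 arrays reached 0.9631. Genes are not independent replicates, so these values describe similarity only. The labels call the arrays biological replicates, but nothing in the sources used here says that they came from separate cultures. All p-values therefore measure only the spread between these samples, which may be technical.

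Jarid2, the targeted gene, was not lower in the arrays labelled null. The brightest of its 3 probe sets read 3335 and 3340 in the Fl/Fl arrays and 4082, 2943 and 2872 in the null arrays at day 0. In Fl/Fl the mean then fell to 1628 ± 227.7 (SD, n = 2) at day 2, 709.5 ± 0.7 at day 4, 535 ± 76.4 at day 6 and 367.5 ± 68.6 at day 8. In null it was 2154.4 ± 396.3 (n = 5), 1340.4 ± 87.2 (n = 5), 1006.2 ± 185.4 (n = 5) and 651.5 ± 379.7 (n = 2) on the same days. Null day 8 replicate 1 read 920 and replicate 2 read 383. Averaged over the days, null lay above Fl/Fl by log2 0.57 (SE 0.113, adjusted p = 0.001), and 18 of 20 null arrays exceeded the Fl/Fl mean of their day. A second probe set gave 0.70 (SE 0.107, adjusted p = 0.000111 among probe sets), with 2207.5 ± 211.4 in Fl/Fl and 2323.3 ± 472.6 in null at day 0. The third gave 0.79 (SE 0.108, adjusted p = 3.35e-05 among probe sets), with 2347.5 ± 173.2 and 2879 ± 40.7 at day 0. At day 0 none of the 3 passed the threshold, with log2 differences of −0.04, 0.06 and 0.30 in the order given here. At days 4 and 6 Jarid2 was higher in null by 0.91 (adjusted p = 0.0149, 5 of 5 null arrays) and 0.89 (adjusted p = 0.0186, 5 of 5). The first adjusted p was 0.123 without Fl/Fl day 4 replicate 1, and the second was 0.277 without Fl/Fl day 6 replicate 2. Where the probe sets lie relative to the deleted part of the gene is not given in the sources used here, so the level cannot check the labels. Genotypes are given as labelled throughout.

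The 20 null arrays fell into 3 sets by the level of Eif2s3y, a gene on the Y chromosome. These sets were formed after the values were seen and are not groups of the study. Eif2s3y read 594 to 981 in 11 null arrays, 217 to 365 in 5 and 11 to 16 in 4, against 130 to 234 in the 10 Fl/Fl arrays. Meg3, an imprinted noncoding RNA, read 21 to 88 in the 11 arrays with high Eif2s3y, 695 to 1902 in the middle 5, 287 to 578 in the 4 near the floor, and 653 to 2579 in Fl/Fl. The ratio of the 3' to the 5' actin control probe sets, a sign of RNA integrity, was 1.288 to 1.43 in the 11 arrays, 1.565 to 2.024 in the middle 5, 1.545 to 1.676 in the 4, and 1.48 to 2.037 in Fl/Fl. Tmem87a read 172 to 348 in the 11 arrays and 9 to 12 in all others. Each day from 2 to 6 held 3 null arrays with high Eif2s3y, 1 of the middle set and 1 near the floor. Day 0 held 2 with high Eif2s3y and 1 of the middle set. Day 8 held 1 of the middle set, replicate 1, and 1 near the floor, replicate 2.

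**Figure D1:**
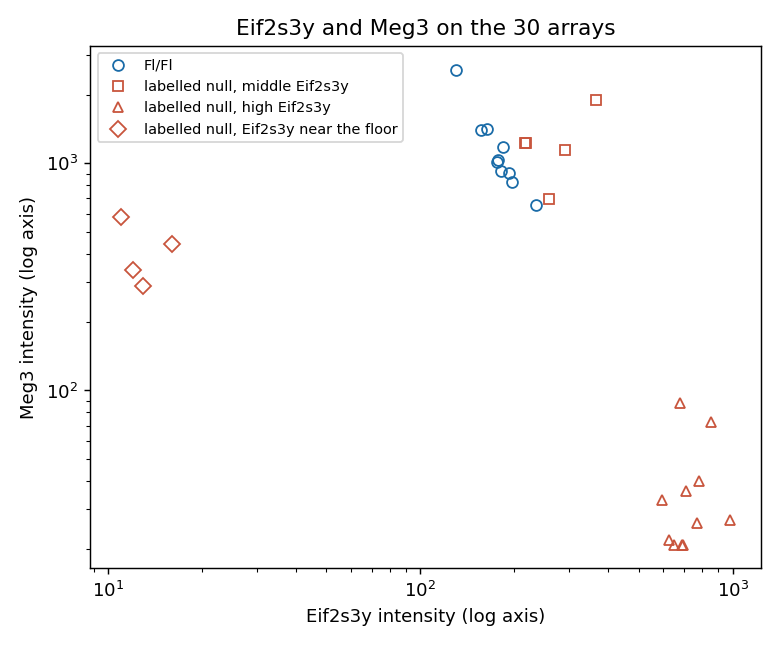
Intensity of Meg3 against intensity of Eif2s3y on log axes, 1 point per array, for the 30 arrays. The 11 null arrays with Eif2s3y at 594 to 981 have Meg3 at 21 to 88, and the 10 Fl/Fl arrays have Eif2s3y at 130 to 234 and Meg3 at 653 to 2579.

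In Fl/Fl cells, pluripotency genes fell and fibroblast and feeder cell markers rose between day 0 and day 8. Pou5f1, which encodes the pluripotency factor Oct4, fell from 7879 ± 1987 to 223 ± 179.6 (SD, n = 2 each; 41.2-fold, adjusted p = 1.24e-09). Sox2, Nanog, Zfp42 and Esrrb fell 23.0-, 25.4-, 24.1- and 45.9-fold. The largest falls were those of Dnmt3l (158.5-fold), a cofactor of DNA methylation, Fgf4 (121.5-fold), Fbxo15 (90.8-fold), Gdf3 (80.6-fold) and Nr0b1 (76.1-fold). The largest rises were those of the matrix genes Col11a1 (134.5-fold), Postn (120.3-fold, from 9.5 ± 0.7 to 1715.5 ± 801.2) and Col3a1 (105.3-fold), and of Wls (124.2-fold), which carries Wnt proteins to the cell surface. Both day 8 arrays lay beyond both day 0 arrays for each of these genes. Mixl1, a gene of the primitive streak, stood at 5 at days 0 and 2, rose to 2037 ± 103.2 at day 4 (log2 7.82 above day 0, adjusted p = 6.52e-06), and read 1750.5 ± 130.8 at day 6 and 87 ± 87.7 at day 8. Fgf5, a marker of the primed epiblast, rose from 7.5 ± 3.5 to 339.5 ± 103.9 at day 4 (adjusted p = 9.32e-06) and was 27.5 ± 10.6 at day 8. The PRC2 genes Ezh2, Suz12 and Eed fell 3.07-, 3.20- and 2.67-fold by day 8.

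Of 35 measured pluripotency genes, 0 rose and 34 fell in Fl/Fl, the same counts as adjusted over the list alone (camera adjusted p = 6.49e-22; adjusted p = 0.00436 with an estimated correlation). Of 29 fibroblast and feeder cell markers, 23 rose and 0 fell, also adjusted over the list alone (adjusted p = 2.52e-15; adjusted p = 0.00367 with an estimated correlation). Of 28 imprinted genes, 12 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.000302; adjusted p = 0.0242 with an estimated correlation), among them Dlk1 (46.9-fold), Gnas (5.90-fold) and Igf2r (7.52-fold). Of 35 cell cycle genes, 1 rose and 30 fell, 1 and 31 adjusted over the list alone (adjusted p = 2.8e-11; adjusted p = 0.203 with an estimated correlation), among them Ccne1 (18.2-fold) and Mcm2 (4.39-fold). Of 35 endoderm genes, 15 rose and 2 fell, also adjusted over the list alone (adjusted p = 9.97e-05; adjusted p = 0.0999 with an estimated correlation), among them the basement membrane genes Sparc (9.49-fold) and Col4a1 (16.2-fold). Of 25 germ cell genes, 0 rose and 11 fell, also adjusted over the list alone (adjusted p = 0.00396; adjusted p = 0.11 with an estimated correlation). In total, 6113 of 18194 genes passed the threshold, 2726 higher and 3387 lower at day 8, and 3673 of them differed at least 2-fold. The adjusted p of Mixl1 at day 8 was 0.311 without Fl/Fl day 8 replicate 1.

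In null cells, pluripotency genes also fell between day 0 and day 8. Of the sets of null arrays by Eif2s3y, only the middle set was present at both days, so a change between them can also reflect the set. Pou5f1 fell from 7324.7 ± 782.4 (SD, n = 3) to 632.5 ± 255.3 (n = 2), 12.0-fold (adjusted p = 7.79e-08), and Sox2, Nanog and Esrrb fell 17.95-, 30.35- and 138-fold. Dnmt3l (398.2-fold), Tex19.1 (150.9-fold), Dppa5a (149.4-fold) and Fgf4 (139.3-fold), all expressed in undifferentiated ES cells, had the largest falls. The largest rises were those of the muscle actins Acta2 (175.2-fold, from 139.7 ± 138.7 to 17602 ± 12388.5) and Acta1 (130.3-fold), the cell junction genes Amot (128-fold) and Dsp (104.3-fold), and Pmp22 (113.6-fold). The keratins Krt8, Krt18 and Krt19 rose 70.2-, 56.7- and 91.9-fold. Mixl1 stood at 4.7 ± 0.6, 5 ± 0 and 9.8 ± 9.6 at days 0, 2 and 4, was 2701 ± 1499.5 (n = 5) at day 6 (log2 8.13 above day 0, adjusted p = 1.51e-08) and 1204 ± 1588.2 at day 8, where the pair of arrays read 2327 and 81. Fgf5 rose to 754 ± 79.2 at day 4 (adjusted p = 4.89e-08) and was 693.4 ± 250.7 at day 6. Both day 8 arrays lay beyond all 3 day 0 arrays for each of these genes.

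Of 35 pluripotency genes, 0 rose and 34 fell in null, 0 and 35 adjusted over the list alone (camera adjusted p = 9.1e-26; adjusted p = 0.00377 with an estimated correlation). Of 35 primitive streak and mesoderm genes, 16 rose and 1 fell, 18 and 1 adjusted over the list alone (adjusted p = 7.45e-06; adjusted p = 0.076 with an estimated correlation). Of 29 fibroblast markers, 16 rose and 0 fell, also adjusted over the list alone (adjusted p = 1.1e-06; adjusted p = 0.0611 with an estimated correlation). In total 6069 genes passed, 2705 higher and 3364 lower, of which 3379 differed at least 2-fold. Of the genes higher at day 8, 2002 were shared with Fl/Fl, where 405.3 would be shared if the lists were independent. Of those lower, 2265 were shared, against 626.2. Without null day 8 replicate 2 the number of genes that passed was 3902.

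Before differentiation, at day 0, null cells had less RNA of Acta2, Dsp, Krt8, Krt18 and Anxa1 and more of Otx2. Otx2, a transcription factor of the primed epiblast, was 57 ± 0 (SD, n = 2) in Fl/Fl and 539.3 ± 60.4 (n = 3) in null, 8.87-fold higher (log2 SE 0.539, adjusted p = 0.00381). Inhbb, a subunit of activin, was 3.89-fold higher (adjusted p = 3.95e-08) and Pou3f1, a gene of the primed epiblast, 3.00-fold higher (adjusted p = 0.0283). Slc39a8, a metal ion transporter, was 5.255-fold higher (adjusted p = 0.0363) and Pnma5 5.74-fold higher (adjusted p = 0.0192). Acta2, smooth muscle actin, was 1398 ± 759.4 in Fl/Fl and 139.7 ± 138.7 in null (14.9-fold lower, log2 SE 0.942, adjusted p = 0.0447). Dsp, a desmosome gene, was 11.2-fold lower (adjusted p = 0.00145). Krt8 and Krt18, keratins of simple epithelia, were 9.355- and 9.275-fold lower (adjusted p = 0.0011 and 0.000432). Anxa1, an annexin, was 8.41-fold lower (adjusted p = 0.0229). In each of these genes 3 of 3 null arrays lay beyond both Fl/Fl arrays, which the rule that named them required. Pou5f1, Sox2, Nanog and Klf4 did not pass at day 0, with log2 differences of −0.09, 0.19, −0.58 and −0.05.

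Of 21 trophoblast genes, 0 rose and 5 fell at day 0, 0 and 7 adjusted over the list alone (camera adjusted p = 2.58e-08; adjusted p = 0.00638 with an estimated correlation), with medians of −0.64 in the arrays with high Eif2s3y and −0.265 in the array of the middle set. The members that fell included Krt18, Krt8, Krt19 (5.875-fold) and Rhox9 (4.11-fold), of which the keratins are found in many epithelia. Of 17 primed epiblast genes, 3 rose and 1 fell, 5 and 1 adjusted over the list alone (adjusted p = 7.05e-05; adjusted p = 0.121 with an estimated correlation). Foxd3 rose 2.04-fold along with Otx2 and Pou3f1, and Krt18 was the member that fell. Of 35 pluripotency genes 0 passed by limma, and 0 adjusted over the list alone, while 2 had an unadjusted p under 0.05 (camera adjusted p = 0.478). Of 29 fibroblast markers 0 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.25), with a median of −0.05 and a mean of −0.52. The member that fell was Col1a1, at 232.5 ± 153.4 in Fl/Fl and 38 ± 45.2 in null (7.437-fold lower, adjusted p = 0.0194; 0.248 without Fl/Fl day 0 replicate 1). S100a6 (2900 ± 205.1 against 1211.7 ± 895.8, adjusted p = 0.223) and Thbs1 (229.5 ± 14.8 against 66 ± 71, adjusted p = 0.251) did not pass. In total 214 genes passed by limma, 45 higher and 169 lower in null, and 68 differed at least 2-fold. The split was 60 and 142 after quantile normalization and 35 and 95, or 130 genes, with centred arrays, and 113 genes passed without the 40% of genes with the lowest mean. Over all genes, the groups did not overlap in 15.3%, where chance gives 20% if no values tie. Between the Fl/Fl day 0 replicates 34.93% of the values were identical, and ties can lower the chance share. This share thus does not show that the groups separate more than by chance, nor that they separate less. The count was 492 without Fl/Fl day 0 replicate 2, 669 without null day 0 replicate 1, 134 without null replicate 2 and 103 without null replicate 3. It was 47 with null replicates 1 and 2 only and 2537 when only the null arrays with high Eif2s3y were used. Leaving out 1 array ended several calls, with the highest adjusted p for Acta2 at 0.196 and for Anxa1 at 0.111 (both without null day 0 replicate 3), for Slc39a8 at 0.213 and for Pou3f1 at 0.261 (both without Fl/Fl day 0 replicate 1), for Pnma5 at 0.1 (without null day 0 replicate 3), and for Rhox9 at 0.127 (without Fl/Fl day 0 replicate 2).

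At day 2, Dsp, Acta2, Krt8, Anxa1 and Ahnak were lower in null. Dsp was 429.5 ± 61.5 (SD, n = 2) in Fl/Fl and 23.6 ± 16.1 (n = 5) in null, 17.6-fold lower (adjusted p = 0.000141). Acta2 was 14.8-fold lower (adjusted p = 0.0385), Krt8 10.8-fold (adjusted p = 0.000283), Anxa1 9.67-fold (adjusted p = 0.0122) and Ahnak, a large membrane scaffold, 8.48-fold (adjusted p = 0.00116). Slc39a8 was 6.94-fold higher (adjusted p = 0.011) and Spon1, a matrix protein, 3.64-fold higher (adjusted p = 0.00108). Lef1, a nuclear effector of Wnt signalling, was 3.16-fold higher (adjusted p = 0.0345), Mcf2 2.98-fold higher (adjusted p = 0.000676) and Sox1, an early neural gene, 2.96-fold higher (48.2 ± 28.1 against 11.5 ± 0.7, adjusted p = 0.0294). In each of these, 5 of 5 null arrays lay beyond both Fl/Fl arrays, as the rule for naming them required. Of 21 trophoblast genes 0 rose and 4 fell, 0 and 8 adjusted over the list alone (camera adjusted p = 1.57e-05; adjusted p = 0.0419 with an estimated correlation). Their median difference from Fl/Fl was −0.63 in the 3 arrays with high Eif2s3y, which had the lowest actin 3'/5' ratios, −0.22 in the array of the middle set and −0.06 in that near the floor. Of 17 primed epiblast genes 2 rose and 1 fell, 3 and 1 adjusted over the list alone (adjusted p = 0.00233; adjusted p = 0.232 with an estimated correlation). In total 113 genes passed, 19 higher and 94 lower, 56 of them by at least 2-fold. Over all genes, 12.9% showed no overlap between the groups, where chance gives 9.5% if no values tie. Between days 0 and 2, 28 lower genes were shared, where 0.9 would be shared if the lists were independent. The count was 244 without Fl/Fl day 2 replicate 2, 66 without null day 2 replicate 4, 69 without null day 2 replicate 5, and 189 without either null day 8 array, which enter through the shared estimate of the spread. It was 1851 with only the null arrays with high Eif2s3y and 61 with replicate number as a replicate block. Without Fl/Fl day 2 replicate 1 the adjusted p was 0.299 for Acta2, 0.111 for Anxa1 and for Slc39a8, 0.198 for Lef1 and 0.166 for Sox1.

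At day 4, Mixl1, Cyp26a1, Aplnr and Lhx1 were lower in null, and Fgf4, Sox2 and Dnmt3b were higher. Mixl1 was 2037 ± 103.2 (SD, n = 2) in Fl/Fl and 9.8 ± 9.6 (n = 5) in null, 169.7-fold lower (log2 SE 0.801, adjusted p = 3.05e-06). Cyp26a1, which breaks down retinoic acid, Aplnr, a receptor of early mesoderm, Lgals3, a galectin, and Lhx1, a transcription factor of early mesoderm, were 68.8-, 44.5-, 43.05- and 33.1-fold lower (adjusted p = 5.49e-05, 0.000906, 2.2e-07 and 0.00191). The endoderm factor Gata6 was 6.26-fold lower (adjusted p = 0.0105) and Cdx2 3.59-fold lower (adjusted p = 4.39e-05). Fgf4, a growth factor of undifferentiated cells, was 16.2-fold higher (adjusted p = 1.81e-05), Sox2 4.58-fold higher (3020.6 ± 766.2 against 638.5 ± 21.9, adjusted p = 3.07e-05) and Dnmt3b, a DNA methyltransferase, 4.15-fold higher (adjusted p = 0.000555). Cbr3, Enpp3, Spon1 and Pdzd4 were 18.1-, 17.2-, 14.4- and 13.5-fold higher. In each of these genes 5 of 5 null arrays lay beyond both Fl/Fl arrays. The rule that named the largest rises and falls required this, but it did not apply to the fixed genes Gata6, Cdx2, Sox2 and Dnmt3b. Pou5f1 was 7099.6 ± 771.3 in null and 4417.5 ± 246.8 in Fl/Fl and did not pass (log2 0.68, adjusted p = 0.204). Nanog did not either (log2 0.03, adjusted p = 1), nor did Eomes, a gene of the primitive streak, at 1155 ± 86.3 in Fl/Fl and 388.4 ± 230 in null (adjusted p = 0.152).

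Of 35 primitive streak and mesoderm genes, 0 rose and 13 fell at day 4, 0 and 15 adjusted over the list alone (camera adjusted p = 6.37e-06; adjusted p = 0.0796 with an estimated correlation). Besides Mixl1 these included Evx1 (15.6-fold), Fgf8 (14.9-fold) and Bmp4 (16.6-fold), genes of the streak and its signals. Of 17 primed epiblast genes 8 rose and 1 fell, 11 and 2 adjusted over the list alone (adjusted p = 6.37e-06; adjusted p = 0.057 with an estimated correlation). Of 35 pluripotency genes 9 rose and 3 fell, 11 and 3 adjusted over the list alone (adjusted p = 0.00114; adjusted p = 0.303 with an estimated correlation). Their median difference from Fl/Fl was 0.82 in the arrays with high Eif2s3y, 0.21 in the middle set and 0.06 near the floor. Of 20 LIF and STAT3 response genes 0 rose and 6 fell, 1 and 9 adjusted over the list alone (adjusted p = 0.00146; adjusted p = 0.057 with an estimated correlation), with Jak1, Stat3 and the LIF co-receptor Il6st lower by 2.735-, 2.108- and 3.996-fold. In total 2112 genes passed, 760 higher and 1352 lower, 1026 of them by at least 2-fold. Over all genes, 24.7% showed no overlap between the groups, where chance gives 9.5% if no values tie. The count was 895 without Fl/Fl day 4 replicate 1 and 1038 without replicate 2. It was 4419 with only the null arrays with high Eif2s3y, in which actin 3'/5' ratios were lowest, and 925 without them. Without Fl/Fl day 4 replicate 2 the adjusted p of Gata6 was 0.106.

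At day 6, Pou5f1, Nanog, Sox2 and Dnmt3b were higher in null. Pou5f1 was 439 ± 77.8 (SD, n = 2) in Fl/Fl and 4093.2 ± 900.6 (n = 5) in null, 9.12-fold higher (log2 SE 0.316, adjusted p = 8.84e-07). Nanog was 6.87-fold (adjusted p = 0.000196), Sox2 5.06-fold (adjusted p = 1.9e-05) and Dnmt3b 3.76-fold higher (adjusted p = 0.00133). The largest rises in null relative to Fl/Fl were those of Apela (35.2-fold), which encodes a secreted peptide of ES cells, the transcription factor Olig1 (32.6-fold), the filament gene Ina (14.4-fold), Enpp3 (13.6-fold) and the kinase gene Pim2 (11.7-fold). Olig1 and Ina were genes of the undifferentiated cells here, which fell 58.6- and 64.9-fold in Fl/Fl from day 0 to day 8. Klf4 was lower in null, at 11.8 ± 3.3 against 136 ± 5.7 (9.03-fold, adjusted p = 0.000177). The matrix genes Col11a1, Col1a1 and Tnc were 34.6-, 27.3- and 27.2-fold lower, and the protease gene Plat and Emp1 27.4- and 24.6-fold. In each of these 5 of 5 null arrays lay beyond both Fl/Fl arrays. The rule that named the largest rises and falls required this, but it did not apply to the fixed genes Pou5f1, Nanog, Sox2, Dnmt3b and Klf4. Mixl1 now read 2701 ± 1499.5 in null and 1750.5 ± 130.8 in Fl/Fl and did not pass (adjusted p = 1). Foxa2, an endoderm factor, was 4 in both Fl/Fl arrays and 67, 283, 4, 9 and 4 in the null arrays (adjusted p = 0.258), with the 2 highest values in the arrays of the middle set and near the floor of Eif2s3y.

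Of 29 fibroblast markers, 0 rose and 14 fell at day 6, 0 and 15 adjusted over the list alone (camera adjusted p = 1.03e-11; adjusted p = 0.013 with an estimated correlation). Their median difference from Fl/Fl was −1.61 in the middle set, −0.77 in the arrays with high Eif2s3y and −1.16 in the array near the floor. Of 35 pluripotency genes 10 rose and 1 fell, 13 and 2 adjusted over the list alone (adjusted p = 0.000158; adjusted p = 0.229 with an estimated correlation), with medians of 0.48 in the arrays with high Eif2s3y, 0 in the middle set and 0.09 near the floor. Of 35 cell cycle genes 12 rose and 2 fell, 24 and 2 adjusted over the list alone (adjusted p = 1.29e-09; adjusted p = 0.229 with an estimated correlation). Cdc20 and Mcm2 were 1.87- and 1.79-fold higher, and the D-type cyclins Ccnd1 and Ccnd2 were 2.37- and 12.5-fold lower. Of 26 PRC2 and PRC1 subunits 5 rose and 3 fell, 7 and 4 adjusted over the list alone (adjusted p = 0.053), with Cbx7 4.375-fold higher and Bmi1 4.33-fold lower. In total 1806 genes passed, 631 higher and 1175 lower, 905 of them by at least 2-fold. The split was 914 higher and 1104 lower after quantile normalization, and 1220 higher and 908 lower with each array centred on its median. Over all genes, 25% showed no overlap between the groups, where chance gives 9.5% if no values tie. With day 4, 243 higher and 468 lower genes were shared, against 26.4 and 87.3 if independent. The count was 813 without Fl/Fl day 6 replicate 1 and 546 without replicate 2. It was 4182 with only the null arrays with high Eif2s3y and 308 without them. The adjusted p of Mcm2 was 0.076 without Fl/Fl day 6 replicate 2.

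**Figure D2:**
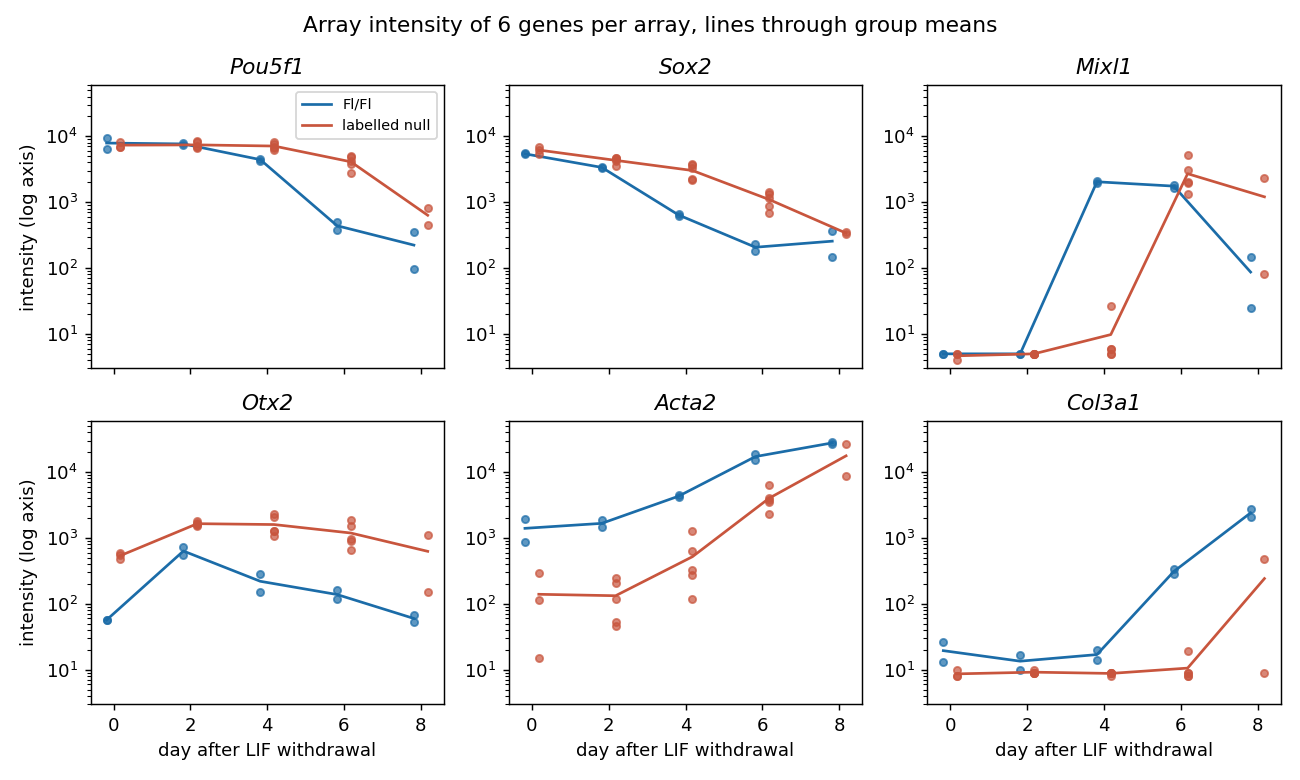
Intensity (log axis) of Pou5f1, Sox2, Mixl1, Otx2, Acta2 and Col3a1 against day after LIF withdrawal, 1 point per array, with lines through the means of the Fl/Fl and null groups. At day 6 Pou5f1 averages 439 in Fl/Fl and 4093.2 in null, and Mixl1 at day 4 averages 2037 in Fl/Fl and 9.8 in null.

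At day 8, fibroblast and feeder cell markers such as Postn were lower in null. Postn, a matrix protein of fibroblasts, was 1715.5 ± 801.2 in Fl/Fl and 40.5 ± 30.4 in null (SD, n = 2 each; 41.7-fold lower, adjusted p = 4.66e-11). Mgp, an inhibitor of calcification in the matrix, was 449 ± 260.2 against 5 ± 0 (46.0-fold, adjusted p = 3.52e-14). Because Mgp read 5 or 6 on all other arrays, the spread in its test came mostly from arrays at the floor. Dlk1 (33.5-fold), Col3a1 (30.1-fold) and Bgn (26.4-fold) were lower too. Igfbp3, which binds insulin-like growth factors, was 10.3-fold higher (adjusted p = 1.09e-08), and Nodal, a ligand that acts in the epiblast, was 5.21-fold higher (1192 ± 15.6 against 239 ± 113.1, adjusted p = 0.000135). Otx2, Lefty1 and Fgf5 were 6.505-, 6.491- and 5.522-fold higher (adjusted p = 0.0116, 0.00183 and 0.0332), and Pou5f1 3.24-fold higher (adjusted p = 0.0132). In each of these genes both null arrays lay beyond both Fl/Fl arrays, which the naming rule required for all of them but Pou5f1. The pair of null arrays differed widely: Otx2 read 1101 and 151, Mixl1 2327 and 81, Acta2 8842 and 26362, Col3a1 9 and 475. Xist, the RNA that coats the inactive X chromosome, was 118.5 ± 47.4 in Fl/Fl and 19 ± 17 in null (6.005-fold lower, adjusted p = 0.0155).

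Of 29 fibroblast markers, 0 rose and 10 fell at day 8, 0 and 14 adjusted over the list alone (camera adjusted p = 2.17e-17; adjusted p = 0.00162 with an estimated correlation), among them Col1a2 (22.8-fold) and Col6a1 (7.76-fold). Of 17 primed epiblast genes 5 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.000298; adjusted p = 0.139 with an estimated correlation). That list's adjusted p was 0.0718 without null day 8 replicate 1. Of 33 Hox genes 0 rose and 5 fell, 3 and 8 adjusted over the list alone (adjusted p = 0.173), among them Hoxd8 (3.22-fold). In total 457 genes passed, 129 higher and 328 lower, 223 of them by at least 2-fold. The split was 211 and 283 after quantile normalization and 209 and 261 with centred arrays, and 299 genes passed without the 40% of genes with the lowest mean. Over all genes, the groups did not overlap in 25.3%, where chance gives 33.3% if no values tie. Since 43.29% of the values were identical between the Fl/Fl day 8 replicates, the chance share can be lower. The share of 25.3% is thus shown to lie neither above nor below it. The count was 280 without Fl/Fl day 8 replicate 2 and 2504 without null day 8 replicate 2, where the lone null array was assumed to vary like the other groups. Without null day 8 replicate 1 the adjusted p of Otx2 was 0.231 and that of Fgf5 0.481. That of Pou5f1 was 0.402 and that of Xist 0.223 without Fl/Fl day 8 replicate 2.

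Averaged over the 5 days, genes of the primed epiblast were higher in null, and fibroblast markers and trophoblast genes were lower. Otx2 was 6.10-fold higher (log2 SE 0.234, adjusted p = 1.89e-07), and Enpp3, Slc39a8, Fgf5, Pim2 and Egln3 were 4.42-, 4.20-, 3.04-, 2.95- and 2.95-fold higher. Tmem87a, 4.16-fold higher (adjusted p = 0.0468), was high only in the 11 null arrays with high Eif2s3y. Col1a1, a chain of type I collagen, was 10.3-fold lower (adjusted p = 4.57e-08), the growth factor gene Igf2 9.01-fold, Acta2 7.22-fold, Anxa1 7.11-fold and Cryab, a small heat shock protein, 6.74-fold. Null arrays lay on the given side of the Fl/Fl mean of their day in 20 of 20 for Otx2, Enpp3, Slc39a8, Fgf5, Egln3, Col1a1, Igf2, Acta2, Anxa1 and Cryab, and in 18 of 20 for Pim2. Bmp4, Krt7 and Pmp22 were 6.31-, 5.62- and 5.81-fold lower, each in 20 of 20. Meg3 was 6.43-fold lower (adjusted p = 0.0192, 17 of 20), with the values of each set of null arrays given above. Sox2, Pou5f1 and Dnmt3b were 2.18-, 2.12- and 2.37-fold higher (20, 15 and 20 of 20), and Klf4 and Esrrb were 2.34- and 1.97-fold lower (15 and 18 of 20). Nanog did not pass (log2 0.09, SE 0.201, adjusted p = 0.835), nor did Ezh2 (log2 0.02, SE 0.125, adjusted p = 0.981). Suz12 and Eed were 1.23- and 1.14-fold higher (adjusted p = 0.0284 and 0.041, 16 of 20 each). Leaving out null day 8 replicate 1 gave 0.0974 for Suz12, leaving out Fl/Fl day 0 replicate 1 gave 0.122 for Eed, and leaving out Fl/Fl day 6 replicate 2 gave 0.0803 for Tmem87a.

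Of 29 fibroblast markers 0 rose and 20 fell in the averaged comparison, 0 and 21 adjusted over the list alone (camera adjusted p = 4.21e-11; adjusted p = 0.0127 with an estimated correlation). Of 17 primed epiblast genes 13 rose and 2 fell, also adjusted over the list alone (adjusted p = 5.82e-08; adjusted p = 0.0127 with an estimated correlation), with Krt18 among the 2. Of 21 trophoblast genes 1 rose and 14 fell, 2 and 15 adjusted over the list alone (adjusted p = 1.17e-06; adjusted p = 0.0127 with an estimated correlation). Of 28 imprinted genes 1 rose and 14 fell, 1 and 16 adjusted over the list alone (adjusted p = 0.000507; adjusted p = 0.023 with an estimated correlation), among them Igf2r (1.83-fold), Ndn (1.73-fold) and Dlk1 (2.49-fold). Their median in the arrays with high Eif2s3y, the middle set and the arrays near the floor was −0.46, −0.275 and −0.48 at day 4 and −0.83, 0 and −0.05 at day 6. At day 8 it was −0.13 in the array of the middle set and −0.64 in that near the floor. Of 35 cell cycle genes 11 rose and 3 fell, 21 and 4 adjusted over the list alone (adjusted p = 5.14e-05; adjusted p = 0.556 with an estimated correlation). Of 35 endoderm genes 1 rose and 12 fell, also adjusted over the list alone (adjusted p = 0.0129; adjusted p = 0.337 with an estimated correlation). Of 35 pluripotency genes 10 rose and 6 fell, 12 and 6 adjusted over the list alone (adjusted p = 0.0171; adjusted p = 0.556 with an estimated correlation). Of 20 LIF and STAT3 response genes 2 rose and 9 fell, 2 and 10 adjusted over the list alone (adjusted p = 0.0286; adjusted p = 0.195 with an estimated correlation), and without Fl/Fl day 0 replicate 2 this list's adjusted p was 0.0636. The list pluripotency and self-renewal, null vs Fl/Fl averaged, had an adjusted p of 0.0542 after quantile normalization and 0.09 with each array centred on its median.

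The other lists did not pass in the averaged comparison, with counts that were alike adjusted over the list alone except where given. Primitive streak and mesoderm genes gave 1 higher and 8 lower of 35 (adjusted p = 0.0969) and neuroectoderm genes 1 and 8 of 28 (2 and 8 adjusted over the list alone, adjusted p = 0.197). PRC2 and PRC1 subunits gave 7 and 6 of 26 (adjusted p = 0.614), with a median of 0.05 and a mean of −0.01; Phc1 was 1.565-fold higher and Phc2 1.83-fold lower. Hox genes gave 0 and 3 of 33 (0 and 1 adjusted over the list alone, adjusted p = 0.922). Non-Hox developmental regulators known as Polycomb targets gave 7 and 16 of 124 (adjusted p = 0.925), with a mean of −0.06, a median of 0 and a test direction that was up. Genes of the two-cell-like state gave 0 and 0 of 10 by limma, with 0 at an unadjusted p under 0.05 (adjusted p = 0.967), with a median of −0.01, a mean of −0.04 and a test direction that was up. Germ cell genes gave 4 and 1 of 25 (adjusted p = 0.137), p53 and stress response genes 1 and 6 of 28 (1 and 7 adjusted over the list alone, adjusted p = 0.195), and glycolysis and hypoxia genes 3 and 4 of 27 (3 and 5 adjusted over the list alone, adjusted p = 0.925). Interferon response genes gave 1 and 3 of 24 (adjusted p = 0.988) and genes of X and Y chromosome dosage 0 and 0 of 5, with 1 at an unadjusted p under 0.05 (adjusted p = 0.385). In total 4224 genes passed by limma, 1411 higher and 2813 lower, of which 363 differed at least 2-fold. The split was 2049 and 2132 after quantile normalization and 1796 and 2414 with centred arrays. The count was 1687 with null replicates 1 and 2 only and 1990 without the null arrays with high Eif2s3y.

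The day 8 against day 0 change differed between the genotypes for genes that included Dsp, Krt8, Igfbp3, Mgp and Postn. Null arrays with high Eif2s3y were present at day 0 but not at day 8, and those near the floor at day 8 but not at day 0. Day and set of null arrays are therefore mixed in this difference. Dsp, Krt8, Krt18 and Krt19, which started lower in null, rose more in null than in Fl/Fl, by log2 3.72 (SE 0.793, adjusted p = 0.02), 3.06 (0.0331), 2.91 (0.0246) and 2.77 (0.0211). Igfbp3 differed by 3.89 (adjusted p = 1.99e-07), with 387.5 ± 64.3 at day 0 and 286 ± 46.7 at day 8 in Fl/Fl against 267 ± 19.2 and 3156 ± 1551.4 in null. Mgp, Postn, Dlk1, Tm4sf1, Bgn and Igfbp5 had lower changes in null than in Fl/Fl, with differences of −5.52, −5.33, −5.10, −5.01, −4.70 and −3.69. Of 29 fibroblast markers 0 were higher and 7 lower, 0 and 9 adjusted over the list alone (camera adjusted p = 7.35e-11; adjusted p = 0.0186 with an estimated correlation). Xist differed by −3.56 (adjusted p = 0.0285). In total 199 genes passed, 74 with a higher and 125 with a lower change in null, 123 of them by at least 2-fold. The count was 92 without the 40% of genes with the lowest mean, 355 without Fl/Fl day 0 replicate 2, 423 without null day 8 replicate 1 and 1281 without null day 8 replicate 2. Leaving out 1 array ended several calls: the highest adjusted p was 0.0658 for Dsp and 0.0938 for Krt19 (without Fl/Fl day 0 replicate 1), and 0.0953 for Krt8, 0.0782 for Krt18 and 0.146 for Xist (without Fl/Fl day 8 replicate 2).

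Over all days, limma's F test found 899 genes whose genotype difference changed with the day, among them Mixl1 (adjusted p = 8.33e-05), Pou5f1 (0.000202), Nanog (0.0016), Sox2 (0.00186), Cdx2 (0.0048) and Klf4 (0.0259). Relative to day 0, the difference in Mixl1 was −7.35 at day 4 (adjusted p = 0.0016) and 0.52 at day 6 (adjusted p = 1). That of Pou5f1 was 3.28 at day 6 (adjusted p = 0.000305) and that of Nanog 3.36 (adjusted p = 0.00501). That of Sox2 was 2.01 at day 4 (adjusted p = 0.0171) and 2.15 at day 6 (adjusted p = 0.00848). The count was 1931 without null day 8 replicate 1 and 2005 without null day 8 replicate 2.

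Null arrays of a given day were also compared with each Fl/Fl day. Null day 4 differed from Fl/Fl day 4 in 2112 genes and from Fl/Fl day 2 in 313. Null day 6 differed from Fl/Fl day 6 in 1806 genes and from Fl/Fl day 4 in 86. Null day 8 differed from Fl/Fl day 8 in 457 genes and from Fl/Fl day 6 in 84. By correlation across genes, 5 of 5 null arrays at day 4 lay nearest to Fl/Fl day 2, and 5 of 5 at day 6 nearest to Fl/Fl day 4. At days 0 and 2 all 3 and all 5 null arrays lay nearest to the Fl/Fl group of the same day. At day 8, replicate 1 lay nearest to Fl/Fl day 6 (r = 0.9826) and replicate 2 to Fl/Fl day 8 (r = 0.9877). These comparisons were chosen after the day-by-day results were seen.

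**Figure D3:**
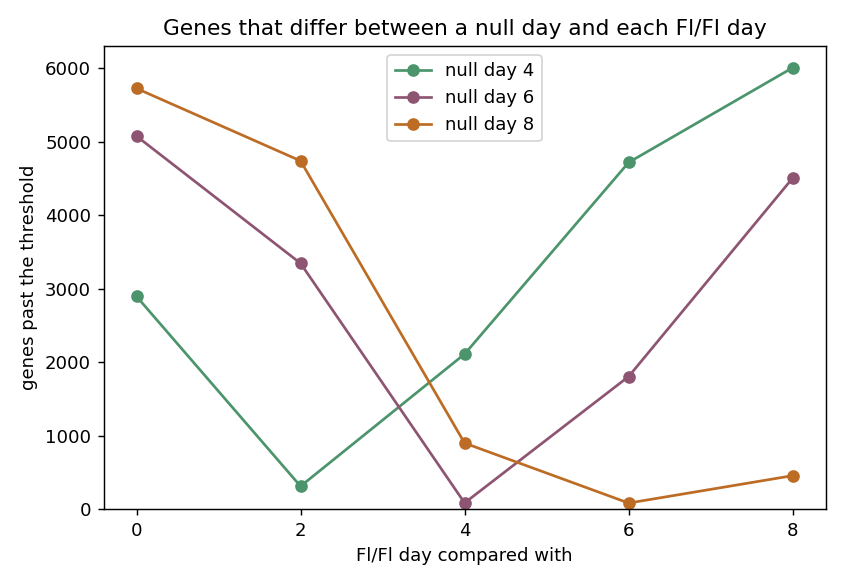
Number of genes past the threshold (adjusted p under 0.05, limma) when the null group of day 4, 6 or 8 is compared with the Fl/Fl group of each day. The lowest counts are 313 for null day 4 against Fl/Fl day 2, 86 for null day 6 against Fl/Fl day 4, and 84 for null day 8 against Fl/Fl day 6.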

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

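Of the tests weighed here, those of the null arrays with high Eif2s3y, of RNA integrity, of a slower course at days 4 and 6 and of other cells at day 0 and the second test of a mislabelled array were chosen after the result was seen, and so were the sets of null arrays by Eif2s3y. At day 6, null replicate 2 stood apart from the other 4 null arrays in Ina, which read 39 against 172 to 271, and in Plat, which read 52 against 13 to 19. Of 68 levels of named genes tested in this way in groups of 5 arrays, 2 lay beyond Dixon's limit, where chance gives about 3.4. The genotype difference changed between days for Pou5f1 (adjusted p = 0.000202), Sox2 (0.00186), Nanog (0.0016), Klf4 (0.0259), Mixl1 (8.33e-05) and Cdx2 (0.0048), by limma's F test. That test passed for 899 genes, and the day 8 against day 0 change differed between the genotypes for 199. By camera, the same difference passed for fibroblast markers (adjusted p = 7.35e-11; adjusted p = 0.0186 with an estimated correlation, 0 members higher and 7 lower). It also passed for LIF and STAT3 response genes (adjusted p = 0.0255; adjusted p = 0.236 with an estimated correlation), mesoderm genes (adjusted p = 0.0451; adjusted p = 0.505 with an estimated correlation), trophoblast genes (adjusted p = 0.0256; adjusted p = 0.292 with an estimated correlation) and cell cycle genes (adjusted p = 0.0171; adjusted p = 0.703 with an estimated correlation). Without null day 8 replicate 1 the adjusted p was 0.244 for LIF response and 0.689 for mesoderm genes. It was 0.172 for trophoblast genes without Fl/Fl day 8 replicate 1, and 0.12 for cell cycle genes without Fl/Fl day 0 replicate 2. Without null day 8 replicate 1 the cell cycle genes passed in the opposite direction (adjusted p = 2.09e-08). Outside the genes named by the annotation, 436 of 9160 probe sets differed between null and Fl/Fl averaged over the days, 94 higher and 342 lower.

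Of 100 splits of the genotype labels within days, only the real 1 gave as many as its 4224 genes in the averaged comparison. This would exclude chance only if the arrays within a day were independent. The highest of the other splits gave 1846 genes and the median split gave 20. The split with 1846 genes kept 8 of the 10 Fl/Fl labels in place. Null arrays of the same number correlated across days at r up to 0.592, which the splits do not take into account.

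The first pattern is the large number of genes that differed at days 4 and 6. If only the null arrays with high Eif2s3y differed from Fl/Fl, the remaining null arrays would call hardly any gene, but they called 925 at day 4 and 308 at day 6, which argues against it; how much of the change they share stays open, with a smallest median ratio to the high-Eif2s3y arrays of 0.482 when 1 Fl/Fl array of the day was used to call the genes and the other to measure the change. RNA integrity as the whole cause is argued against too. With the same separation, at least 80.6% of the genes called from the high-Eif2s3y arrays kept their direction in the remaining null arrays. Actin 3'/5' ratios of the remaining null arrays were 1.625 and 1.621 at day 4, against 1.573 and 1.526 in Fl/Fl. At day 6 they were 1.565 and 1.545, against 1.546 and 1.48 in Fl/Fl. They thus did not share the low ratios of the high-Eif2s3y arrays, which were 1.288 to 1.43 over all days. A slower course in null may account for much of the pattern as a hypothesis: comparing null with the preceding Fl/Fl day left 313 genes in place of 2112 at day 4, a ratio of 0.148, and 86 in place of 1806 at day 6, a ratio of 0.048. Not all genes went with such a course. Otx2 read 539.3 in null and 57 in Fl/Fl at day 0, and 633 in Fl/Fl at day 2. Tfcp2l1 fell in Fl/Fl from 882.5 at day 0 to 93.5 at day 2. At day 4 it was lower in null, at 17.8 against 79 (limma adjusted p = 0.00318). At day 2 Nanog (751 against 1444) and Esrrb (100.2 against 243.5) were lower in 5 of 5 null arrays, but did not pass. Whether the loss of Jarid2 or a difference between cell lines slowed the course stays open, because no label separates line from genotype and Jarid2 RNA was not lower in the arrays labelled null.

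The second pattern is the distance between the pair of null day 8 arrays. If replicate 2 were a mislabelled Fl/Fl day 8 array, it would not lean to the null side in genes called at earlier days. Measured from the Fl/Fl day 8 mean, 46.4% of 459 such genes did so in replicate 2, against 87.8% in replicate 1. The Fl/Fl replicates, each measured from the other, gave 54.9% and 42.7%, which are 2 sides of 1 comparison. A second test on 364 genes called from null arrays with Eif2s3y near the floor also gave 46.4%, against 89.6% in replicate 1. These shares go with a wrong label, but an array that had caught up with Fl/Fl could also give them, so they cannot decide. Eif2s3y read 11 in replicate 2, within the 11 to 16 of the null arrays near the floor. It read 130 to 234 in Fl/Fl, with 163 and 130 at day 8. These levels argue against an array of the Fl/Fl cells measured here. A wrong label of another kind stays open. Different cell lines or clones may likewise account for the distance: the difference between the 2 arrays at day 8 correlated with the mean difference between the same sets at days 2, 4 and 6 at r = 0.491 across 7455 genes. With each day by itself r was 0.146, 0.287 and 0.624. Replicate 1 lay nearest to Fl/Fl day 6 and replicate 2 to Fl/Fl day 8. The correlation therefore cannot tell different lines from arrays at different points of the course.

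The third pattern is the lower level of Krt8, Dsp, Acta2 and other genes in null at day 0. If Fl/Fl day 0 cultures held cells like those of Fl/Fl day 8, the abundant transcripts of day 8 would exceed null at day 0 by what a share of 10.36% needs. Of 89 such genes that were low in null at day 0, 83 lay below that excess, at a median ratio of 0.367 (quartiles 0.207 and 0.594). In both Fl/Fl arrays 7 had under 10% of it. Postn read at most 10, where an excess of 118.1 over null was needed, and Col11a1 at most 12, with 196.2 needed. The 10.36% came from 36 genes that were lower in null at day 0 and rose by day 8, so it may be too high. At a share of 3.8%, scaled to the median ratio, 3 genes had under 10% of the excess. These values argue against cells of that make-up at a share of 10.36% and leave a smaller share open. Feeder fibroblasts stay open: 6 of 29 fibroblast markers, or 20.7%, were at least 2-fold higher in Fl/Fl, and of these Col1a1 passed (adjusted p = 0.0194). A few spontaneously differentiating cells of another kind, including only some of the kinds present at day 8, a difference between lines and an effect of the genotype stay open too and were not tested.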

How the results depend on the processing

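The settings that use the level of Eif2s3y were chosen after the data were seen; all other settings were chosen before. For most genes named in the text, the side of the threshold held, and so did the direction of those that passed: after quantile normalization in 913 of 929 gene results (9 weaker, 7 stronger), with centred arrays in 902 (16 and 11), with a trend in the prior variance in 928 (0 and 1), with a pseudocount of 1 in 924 (2 and 3) or 4 times as large in 914 (8 and 7), and with the mean of the probe sets in 890 (27 and 12). Fewer held with array weights, at 832 (47 weaker, 50 stronger), with null replicates 1 and 2 only, at 786 (137 and 6), without the null arrays with high Eif2s3y, at 772 (144 and 13), without those near the floor, at 839 (10 and 80), with a 2-fold limit, at 841 (88 and 0), with the level of Eif2s3y as a fixed block, at 885 (6 and 36, with 2 reversed), and with the replicate block, at 881 (40 and 8). With only the arrays of the groups compared 604 of 824 held (205 and 15), and with only the null arrays with high Eif2s3y 307 of 399 (2 and 90). Among the results that held, genes that did not pass changed sign in 5 after quantile normalization, 15 with centred arrays, 17 with the mean of the probe sets, 17 with array weights, 37 with null replicates 1 and 2 only, 43 without the null arrays with high Eif2s3y and 36 with the replicate block. Counts of genes stayed within 1.5 times the main count under quantile normalization, both pseudocounts, the mean of the probe sets, the trend and the replicate block within genotype. The cause was not tested for the changes below, except where the setting itself uses fewer arrays, fewer genes or a further limit. All alternatives chosen beforehand were run, except that the 2-fold limit was not set on the F test. A fit of only the arrays compared has no separate value for the averaged comparison and the F test, which use all 30. The median intensity of 10 or 11 lies near the floor, so for much of the arrays signal over background limits which changes can be seen, and fold changes of weak genes are understated.

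The main counts were 214 at day 0, 113 at day 2, 2112 at day 4, 1806 at day 6, 457 at day 8, 4224 averaged, 6113 for the Fl/Fl course, 6069 for the null course, 199 for the difference between the courses and 899 by the F test. With each array centred on its median, day 0 gave 130. Without the 40% of genes with the lowest mean, day 0 gave 113, day 8 gave 299 and the difference 92. With array weights, day 2 gave 657, day 4 gave 4262, day 6 gave 5186, day 8 gave 111, the null course 3236, the difference 60 and the F test 2243. With null replicates 1 and 2 only, the counts were 47, 35, 815, 333 and 228 at days 0 to 8, 1687 averaged, 82 for the difference and 273 by the F test. With only the arrays of the groups compared, day 0 gave 123, the Fl/Fl course 3960, the null course 955 and the difference 110. With at least a 2-fold change, the counts were 68, 56, 1026, 905 and 223 at days 0 to 8, 363 averaged, 3673 and 3379 for the courses and 123 for the difference; Jarid2, at 0.572, lay below that limit. With an estimated correlation, 11 list shifts passed in place of 41 in the 6 contrasts chosen beforehand, and 13 in place of 61 when days 2, 4 and 6 are added.

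With replicate number as a replicate block, day 2 gave 61. Nothing in the labels pairs the samples: 13 of 50 correlations between arrays of the same replicate number across genotypes passed 0.1 (range −0.224 to 0.407). Across days within a genotype, 24 of 32 such correlations passed 0.1 in null (range −0.403 to 0.592) and 6 of 20 in Fl/Fl (range −0.034 to 0.209). With the replicate block within genotype the consensus correlation was 0.102. Replicate numbers in null do not follow the sets by Eif2s3y: replicate 2 had high Eif2s3y at day 0, a middle level at day 2 and a level near the floor at day 4. The block therefore does not measure how alike arrays of the same set are across days.

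Without the null arrays with Eif2s3y near the floor, day 0 gave 430, day 2 gave 343, day 6 gave 2955, day 8 gave 2623, the null course 4042, the difference 1441 and the F test 2371. Without the null arrays with high Eif2s3y, the counts were 364, 53, 925, 308 and 270 at days 0 to 8, 1990 averaged, 385 for the difference and 563 by the F test; days 0 and 8 hold 2 and 0 such arrays, so at day 8 the change came through the shared spread. With only the null arrays with high Eif2s3y, day 0 gave 2537, day 2 gave 1851, day 4 gave 4419 and day 6 gave 4182; day 8 holds none. With the level of Eif2s3y as a fixed block, day 2 gave 250, day 8 gave 1213, the difference 327 and the F test 1853.

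With each array left out in turn, the counts ranged from 103 to 669 at day 0, 66 to 244 at day 2, 895 to 2654 at day 4, 546 to 2484 at day 6, 280 to 2504 at day 8, 3392 to 5345 averaged, 4465 to 6425 for the Fl/Fl course, 3902 to 6108 for the null course, 162 to 1281 for the difference and 691 to 2005 by the F test. Jarid2 averaged ranged from 0.447 to 0.698, and 35 to 47 list shifts passed in the 6 contrasts chosen beforehand (57 to 69 in all 9). The lowest counts came without null replicate 3 at day 0, null replicate 4 at day 2, Fl/Fl replicate 1 at day 4, Fl/Fl replicate 2 at day 6 and Fl/Fl replicate 2 at day 8; the highest at day 8 came without null replicate 2. Where 1 array was left in a group, the lone sample was assumed to vary like the other groups.

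Few results reversed. With the level of Eif2s3y as a fixed block, Eif2s3y itself became −0.259 averaged and −0.674 at day 6, which follows from the block's construction. With each array left out in turn, Ezh2 at day 8 ranged from −0.866 (without null day 8 replicate 1) to 0.939 (without null day 8 replicate 2). The adjusted p of the cell cycle list at day 8 was 0.000298 (adjusted p = 0.583 with an estimated correlation) and ranged from 7.17e-26 (without null day 8 replicate 2) to 0.00415 (without Fl/Fl day 8 replicate 2). It was 6.29e-11 in the opposite direction without null day 8 replicate 1. In the difference between courses it was 0.0171 (adjusted p = 0.703 with an estimated correlation) and ranged from 2.33e-24 (without null day 8 replicate 2) to 0.12 (without Fl/Fl day 0 replicate 2), and was 2.09e-08 in the opposite direction without null day 8 replicate 1. That of the glycolysis list at day 0 was 0.0418 (adjusted p = 0.811 with an estimated correlation) and ranged from 5.36e-07 (without Fl/Fl day 0 replicate 2) to 0.289 (without null day 0 replicate 3), and the list turned without Fl/Fl day 0 replicate 1, at 0.248.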

Other observations

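The tests of lists at days 4 and 6 were chosen after the data were seen. At day 4, 5 of 24 interferon response genes were lower in null and 1 was higher; the list passed by camera but not with an estimated correlation (adjusted p = 0.00447; adjusted p = 0.0796 with an estimated correlation). H2-D1, a class I histocompatibility gene, was 1308.5 ± 74.2 (SD, n = 2) in Fl/Fl and 448.4 ± 174.1 (n = 5) in null (3.06-fold lower, adjusted p = 0.00102), and B2m, its light chain, was 1.98-fold lower (adjusted p = 0.00149). Bst2 was 1.65-fold higher (adjusted p = 0.0219). In each of these 5 of 5 null arrays lay beyond both Fl/Fl arrays. Adjusted over the list alone, 1 rose and 8 fell. From day 0 to day 8, B2m rose and Bst2 fell both in Fl/Fl (12.25- and 4.752-fold) and in null (9.755- and 4.767-fold). Their differences at day 4 thus lay on the side of the earlier days. The adjusted p of Bst2 was 0.266 without Fl/Fl day 4 replicate 1. Of 35 endoderm genes 0 rose and 9 fell at day 4, also adjusted over the list alone (adjusted p = 0.014; adjusted p = 0.298 with an estimated correlation), with Cited1, a transcriptional coactivator, 13.6-fold and Nid1, a basement membrane gene, 5.89-fold lower (adjusted p = 4.14e-07 and 0.000871, 5 of 5 null arrays each). The stress response genes Atf3 and Cdkn1a, which encodes a cell cycle inhibitor, were 5.55- and 3.06-fold lower (adjusted p = 0.00158 and 0.00885, 5 of 5 each). That of Cdkn1a was 0.113 without Fl/Fl day 4 replicate 1. Their list of 28 had 0 higher and 7 lower, 0 and 8 adjusted over the list alone, and did not pass by camera (adjusted p = 0.0515).

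At day 6 genes of the neuroectoderm list differed from Fl/Fl in both directions in null. Olig2, a factor of the ventral neural tube, was 8 ± 0 in Fl/Fl and 132.2 ± 81.1 in null (9.72-fold higher, adjusted p = 0.000106), while Ncam1, a neural adhesion molecule, and Tubb3, a neuronal tubulin, were 8.13- and 4.12-fold lower (adjusted p = 3.32e-08 and 0.000202), in 5 of 5 null arrays each. In Fl/Fl, Olig2 fell from 488.5 ± 205.8 at day 0 to 12.5 ± 4.9 at day 8, and Ncam1 rose from 8 ± 1.4 to 220.5 ± 12. In null, Olig2 read 243.7 ± 66.3 at day 0. The higher Olig2 and the lower Ncam1 in null at day 6 thus both lay on the side of the earlier days. Of 28 neuroectoderm genes 1 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.246). At day 8, 0 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.00327; adjusted p = 0.161 with an estimated correlation), with Tubb3 5.60-fold and Dlx2 3.02-fold lower in both null arrays. Without null day 8 replicate 1 that list's adjusted p was 0.124.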
